A study of Mus musculus with 2 samples.

How the data were processed

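Total RNA of cells labelled GT1-7 was amplified, labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays with probes of 60 nt, per the labels' protocols and the file headers. Both arrays lay on 1 slide, so slide is not a difference between the groups. Each array held 62976 spots, of which 59305 were not controls; 399 probes were printed 10 times and 33 were printed 2 times.

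The deposited scanner files give each spot's intensity on a linear scale. Per the file headers, the scanner software (Feature Extraction 10.7.1.1) subtracted background and detrended the signal within each array, and gave an error estimate for each processed signal; the submitters' processing notes name version 9.5.1.1 instead. The detection-limit metric in the headers was outside its range for the vehicle array and inside it for the GnRH array. The authors' deposited value table holds linear intensity values with 1 row per probe. Its columns had medians of 28.43 and 28.44. On the log2 scale they correlated at r = 1.00 across probes with the scanner values of their arrays, which settles the scale. The arrays also correlated with each other at r = 0.997 across genes, so the direction rests on the differences. Differences between the columns correlated at r = 0.998 with those of the scanner values over 29665 probes. The columns' sorted values were nearly equal, as quantile normalization leaves them, but the method was not given in the sources used here.

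Control spots were left out, as were spots marked as outliers, 121 on the vehicle array and 94 on the GnRH array, and log2 processed signals of the kept spots of a probe were averaged. The main values were these averages minus each array's 75th percentile over the probes (578 on the vehicle array and 541 on the GnRH array before the log). A probe counted as well above background when at least 50% of its kept spots carried that mark. A gene's value was its brightest probe among those well above background on both arrays; 5913 of 21219 genes had over 1 such probe. Of 55681 probes, 27235 were named through their accession in a RefSeq table (GRCm38.p6, used for names only), 2838 of them with a symbol other than the file's, and the rest kept the file's name. Differences are GnRH minus vehicle. Errors are those of the scanner software, combined over both arrays, with spots of a probe taken as independent. For bright genes they mostly reflect the software's multiplicative error setting of 0.1 and not a spread measured on these arrays.

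With 1 array per group, no test was made. Genes were counted at 2-fold. A gene above background on 1 array only was given a lower bound, its normalized signal on the bright array over the higher of its own signal and the lowest signal well above background on the other array. The 27 gene lists, the counting threshold, the rule for named genes and all alternatives except those said to be added were fixed before the data were examined. A list's median was placed among 10000 random lists matched on mean signal in 20 bins, for lists with at least 4 measured members.

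The rule for named genes took up to 15 genes in each direction with the largest differences of at least 2-fold among genes with a symbol and a mean signal at or above the 25th percentile (15 higher and 6 lower met it), and up to 5 in each direction with the largest bounds. It always took Gnrh1, Gnrhr, Fos, Egr1 and Erbb4, and up to 5 members of each list with the largest differences. Other genes are named as chosen after their values were seen, and some genes that the rule takes are not reported here.

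After the data were seen, areas were sought where neighbouring spots differ together. The median log2 difference of the spots within 2 rows and columns of a spot, itself left out, was taken. Connected areas of at least 4 spots with a median of 0.3 or more in size were kept and widened by 2 spots. The limit was passed by 190 spots, and by 0 when positions were shuffled. The 3 areas held 480 non-control spots (0.809%).

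The steps were tested on simulated data for this comparison, with the vehicle array plus spot noise on both sides and 21561 genes. That noise came from replicate spots of the vehicle array. It held no variation between labellings, hybridisations or cultures, so the shares below are not error rates of the real arrays. Of 50 genes each, 2% were counted after a planted 1.5-fold change, 38% after 2-fold, 100% after 4-fold and 100% after 8-fold, and 0% of 21341 unchanged genes were. Alternatives changed the scaling (median, quantile, lowess with a fraction of 0.3), the background correction (normexp with an offset of 50, or none), the source of values, the filter on dim probes, the rule for several probes, outlier spots, the threshold, the background call and the summary and matching of lists. Added later were leaving out the areas, leaving out list members that other lists hold, and the looser background call for counts at 2-fold and for lists; that call was planned only for genes above background on 1 array. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.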

Results

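The data were 2 arrays of the 1-colour (Cy3) kind, measuring RNA labelled as that of GT1-7, a line of immortalised mouse hypothalamic neurons known for secreting gonadotropin-releasing hormone (GnRH), the decapeptide that drives pituitary gonadotropin release. The vehicle group (1 array) received DMSO for 30 min and the GnRH group (1 array) received 50 nM of the peptide for 30 min. The free-text description of both samples instead names 100 nM bradykinin and the A549 line, and every other label names GT1-7; the groups here follow the treatment labels. Gnrh1 was not well above background on either array, while the pituitary gonadotrope genes Cga, Nr5a1 and Pitx1 were on both, so the cells are called here only by their label. Each array carried 55681 distinct non-control probes. The share of non-control spots well above background was 55.2% on the vehicle array and 56.9% on the GnRH array, and no spot was saturated. With 1 array per group there was no replicate check of any difference, no test across cultures was possible, and the number of arrays limits the precision; all values below describe these 2 arrays.

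The comparison asked which transcripts differed after 30 min of exposure of the cells labelled GT1-7 to the peptide. The genes that stood highest in the GnRH array were immediate-early genes. Egr1, a zinc-finger transcription factor, was 354-fold higher, at a processed signal of 73.5 in the vehicle array and 24361 in the GnRH array, a log2 difference of 8.47 ± 0.22 (scanner error). The AP-1 subunit gene Fosb was 82.4-fold higher (log2 difference 6.36 ± 0.22). Fos, measured on 10 spots per array, was 63.3-fold higher (5.98 ± 0.07), and the activity-regulated neuronal transcription factor gene Npas4 was 55.6-fold higher (5.80 ± 0.20). With no background correction Npas4 was at 5.68, Fosb at 5.35 and Fos at 5.26, so their order depends on that step. Fosb and Fos moved there by more than the scanner error. The receptor for the peptide, Gnrhr, was bright on both arrays and differed by -0.03 ± 0.20 on the log2 scale.

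Among 21219 genes well above background on both arrays, 66 were at least 2-fold higher and 28 at least 2-fold lower in the GnRH array. Of these, 41 higher and 13 lower genes had a gene symbol. Neighbouring spots of unrelated genes differed together in 3 small areas of the array. Without those areas, a choice made after seeing the data, 45 genes were higher and 14 lower, with 30 and 5 symbols. Of the 30 higher genes with a symbol outside the areas, 22 belonged to a gene list fixed before the data were examined, and none of the 5 lower ones did. These 5, which miss the signal limit of the rule for named genes, were Aplnr (-1.25 ± 0.33), Tex19.2 (-1.21 ± 0.22), Nhsl2 (-1.11 ± 0.36; 0.11 on its other measured probe), H2-DMa (-1.09 ± 0.22) and Wnt10b (-1.06 ± 0.36), with vehicle signals of 40.1 to 155. The remaining genes moved little, with 97.9% of all measured genes within 1.5-fold and a median log2 difference of -0.01. Scanner error gave a typical difference an error of about 0.20 on the log2 scale, mostly from the software's multiplicative error setting of 0.1. Of the 399 probes printed 10 times, 261 had all kept spots well above background on both arrays. Single spots of these 261 probes varied by 0.13 (SD of a log2 difference). Among these 261 probes only that of Fos differed 2-fold. These errors are technical and do not include variation between cultures.

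**Figure D1:**
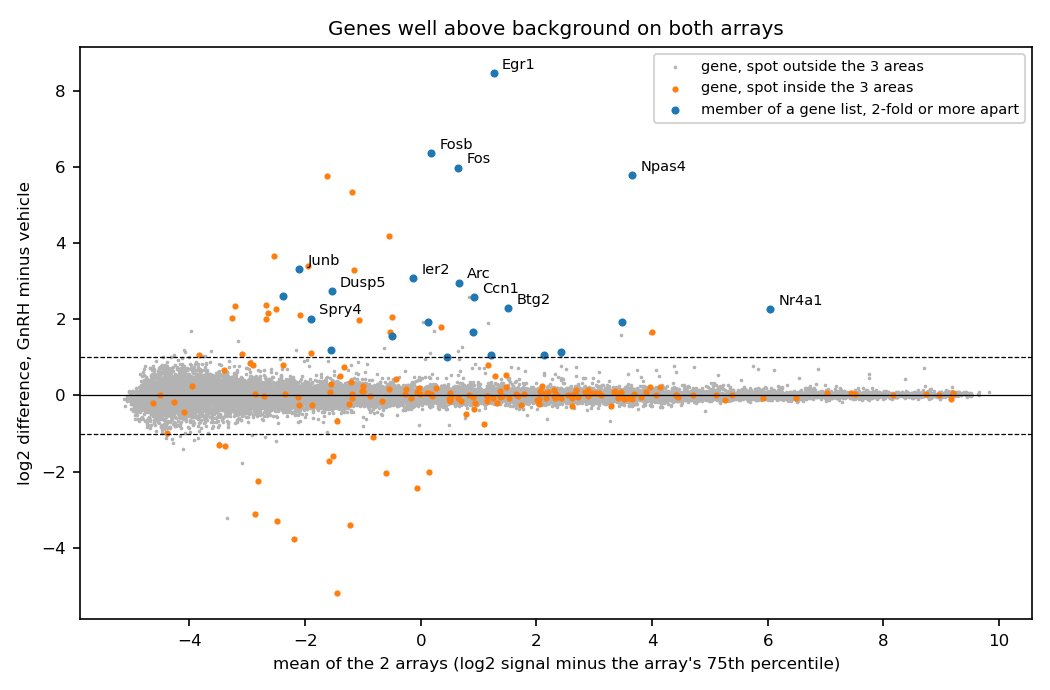
Log2 difference (GnRH minus vehicle) against the mean normalized log2 signal of the 2 arrays, 1 point per gene well above background on both. Dashed lines mark 2-fold; Egr1 sits highest at 8.47, the labelled genes are list members outside the 3 areas, and orange points lie inside the areas.

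The list of immediate-early transcription factors was shifted furthest. All 22 measured members were above 0 and 12 were at least 2-fold higher. The median log2 difference was 1.37, above all of 10000 random lists of the same size matched on signal (percentile 100). The central 95% of random medians ran from -0.05 to 0.04. Without the members that other lists hold, the median was 0.84 over 18 genes (percentile 100). Beside Egr1, Fosb, Fos and Npas4, the AP-1 gene Junb was 9.91-fold higher (3.31 ± 0.23), Ier2 8.50-fold (3.09 ± 0.21), the antiproliferative gene Btg2 4.90-fold (2.29 ± 0.20) and the orphan nuclear receptor gene Nr4a1 4.82-fold (2.27 ± 0.20). Junb fell to 2.19 with no background correction. Nr4a1 was already bright without the peptide, at 17380 in the vehicle array and 78369 in the GnRH array. Jun (1.93), Atf3 (1.67) and Srf (1.07), chosen after their values were seen, were also over 2-fold higher. Myc differed by 0.08 and Nr4a2 by 0.15. Egr2 was well above background in the GnRH array only and was at least 143-fold higher there; such bounds set the bright signal against the lowest signal well above background on the other array.

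MAP kinase phosphatases, which switch off MAP kinases, had a median of 0.78 over 10 measured members (percentile 100), with 3 at least 2-fold higher. Dusp5 was 6.69-fold higher (2.74 ± 0.22) and Dusp6 3.78-fold (1.92 ± 0.20). Dusp1 was 3.45-fold higher (1.79 ± 0.20). Its only measured probe lay in one of the 3 areas, and the spots around it had a median log2 difference of 1.58. Without the areas the list median was 0.74 over 9 members (percentile 100). Dusp7 differed by -0.07. The inducible signalling inhibitors and effectors had 21 measured members, all above 0, with 4 at least 2-fold higher and a median of 0.45 (percentile 100). Arc, which encodes an activity-regulated synaptic protein, was 7.79-fold higher (2.96 ± 0.20), and Spry4, a receptor tyrosine kinase signalling inhibitor, 4.06-fold (2.02 ± 0.21). Gem was 2.22-fold higher on its brightest probe (1.15) and 0.72 on its other probe. Zfp36, an RNA-decay factor of the same list, was above background in the GnRH array only, at least 6.77-fold higher; Rrad was too, at least 5.24-fold, with its spot inside the areas.

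The CREB-linked inducible genes had 20 measured members, all above 0, a median of 0.41 and 4 members at least 2-fold higher (percentile 100). Those 4, Fosb, Fos, Nr4a1 and Dusp1, also belong to other lists, and the spot of Dusp1 lay inside the areas. Without shared members the median was 0.34 over 15 genes (percentile 100), with Per2 at 0.65 and Bdnf at 0.60. SRF and actin-linked targets had a median of 0.15 over 14 members (percentile 100), with 2 at least 2-fold higher. These were the matricellular gene Ccn1, 6.02-fold higher (2.59 ± 0.20), and Fhl2, 2.95-fold (1.56 ± 0.21), while the smooth muscle gene Tagln differed by -0.11. Cnn1 was above background in the vehicle array only, with a bound of 2.09-fold lower in the GnRH array. NF-kB and cytokine genes had a median of 0.21 over 14 members (percentile 100), and the chemokine gene Cxcl10 was the only one of these at least 2-fold higher (1.05 ± 0.20), followed by Nfkbiz at 0.93. Tnf was above background in the GnRH array only, at least 2.21-fold higher.

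**Figure D2:**
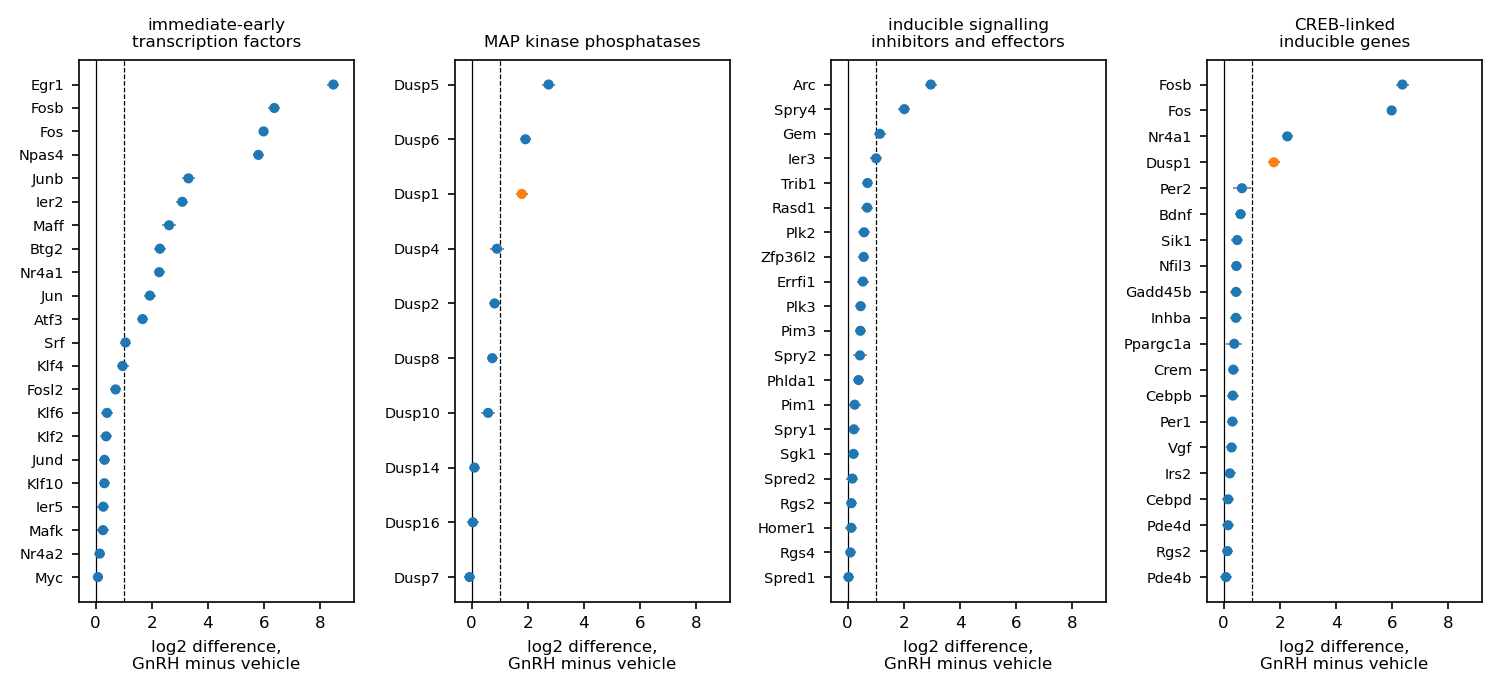
Log2 difference (GnRH minus vehicle) of each measured member of 4 gene lists; bars are scanner error and the dashed line marks 2-fold. All members of the immediate-early list lie above 0, from Myc at 0.08 to Egr1 at 8.47, and the orange point is Dusp1, whose spot lay inside 1 of the 3 areas.

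ErbB receptors, ligands and sheddases had a median of 0.11 over 13 members (percentile 97.9), a place outside the central 95% that was lost under 6 alternatives, among them the authors' value table (97.3), and was lowest with the stricter filter (88.2). The EGF receptor ligand gene Hbegf was 2.28-fold higher (1.19 ± 0.21) and was the only member past 2-fold, with Erbb4 at 0.12 ± 0.20 and Egfr at -0.10. The other Erbb4 probe was not well above background on either array (signals of 3.49 in the vehicle array and 5.88 in the GnRH array). The unfolded protein and integrated stress response list had no member past 2-fold and a median of 0.16 over 16 members (percentile 100), led by Chac1 at 0.67 and Ddit4 at 0.66. The p53 targets had a median of 0.09 over 15 members (percentile 100), with Btg2 the only one past 2-fold; without the members that other lists hold the median was 0.04 (percentile 97.7). Cholesterol synthesis genes had a median of 0.04 over 18 members (percentile 99.1; 93.3 with unmatched random lists and 96.2 as a mean) and none past 2-fold.

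Genes of the GnRH neuron lists and those that carry the receptor's signal did not differ 2-fold. GnRH receptor signalling components had a median of -0.02 over 34 members (percentile 30.9). Neurosecretory and vesicle genes had a median of -0.03 over 18 members (percentile 11.5), and voltage-gated ion channels -0.03 over 26 (percentile 23.0). The GnRH neuron identity list had a median of 0.03 over 19 of its 23 genes (percentile 86.7), from Otx2 at -0.59 to Dlx5 at 0.62. Gnrh1 itself was not well above background on either array with either of its 2 probes (chromosome 14, 68363316 to 68363375 and 68364362 to 68364421, build mm9), so no fold is given; Six6, Meis1 and Nhlh2 of the same list were not either. The Gnrhr probes lay on chromosome 5 at 86611152 to 86611211 and 86613585 to 86613644 (mm9), with vehicle signals of 14861 and 3785.

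Medians lay inside the central 95% of random lists for heat shock proteins (0.03, percentile 93.3), hypoxia and glycolysis genes (0.03, 86.0), G1/S genes (0.01, 71.0) and G2/M genes (0.00, 72.2). The same held for interferon-stimulated genes (-0.04, percentile 20.7), replication-dependent histones (0.04, 88.2), ribosomal proteins (0.03, 85.1) and commonly used reference genes (0.01, 71.1). The reference gene Gapdh differed by 0.00, while the 13 measured reference genes ran from -0.07 to 0.71, with 1 past 1.5-fold. Of the markers of other cells, oligodendrocyte (6 of 9 measured, median -0.03, percentile 40.0), microglia and macrophage (5 of 9, -0.04, 28.3) and fibroblast and endothelial markers (4 of 11, -0.02, 44.5) lay inside that range too. The 4 measured gonadotrope and pituitary markers had a median of -0.08 (percentile 1.51), which turned to 0.04 with the mean over probes or no filter on dim probes; that place was lost under 5 alternatives. Their signals in the vehicle and GnRH arrays were 80508 and 69481 for Cga, the glycoprotein hormone alpha subunit gene, 33412 and 28614 for Nr5a1, 48204 and 44001 for Pitx1, and 71.5 and 72.1 for Lhb. The other 6 markers of that list, Fshb, Prl, Gh, Pomc, Tshb and Pou1f1, were not well above background on both arrays. Only 3 of 8 astrocyte markers were measured, so they give values only, with Slc1a2 at 0.07, Aqp4 at 0.05 and Aldh1l1 at -0.10. No list had a member, measured on both arrays, that was at least 2-fold lower.

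The genes of the rule that no list holds, and that were measured on both arrays, had spots in the 3 areas of the array. Among the 15 highest genes of the rule, these were Foxr1 (5.76 ± 0.32), the embryonic haemoglobin gene Hbb-bh1 (2.10 ± 0.22) and Yipf7 (1.99 ± 0.20). All 6 lower genes of the rule lay there too: Ppp2r5e (-2.44 ± 0.21), Gabrr1 (-2.03 ± 0.21), Ttc14 (-2.01 ± 0.20), Ntrk3 (-1.72 ± 0.21), Pax6 (-1.59 ± 0.15) and Insyn2b (-1.09 ± 0.21). Other probes of Ttc14 and Ntrk3 outside the areas gave medians of -0.19 and -0.06.

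Bounds of at least 2-fold were met by 67 genes above background in the GnRH array only and by 69 in the vehicle array only. Without the areas the counts were 29 and 29. Beside Egr2, which lay outside the areas, the largest bounds among genes with a symbol were for Tbx19 (at least 68.6-fold), Htr2a (62.8), Ccdc74a (36.0) and Vmn1r40 (30.5) in the GnRH array. In the vehicle array they were for Tcl1b3 (67.4), Arhgef5 (49.3), Vmn2r58 (29.2), Olfr312 (14.9) and Mrgprb4 (14.04). The spots of these 9 genes all lay inside the areas.

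**Figure D3:**
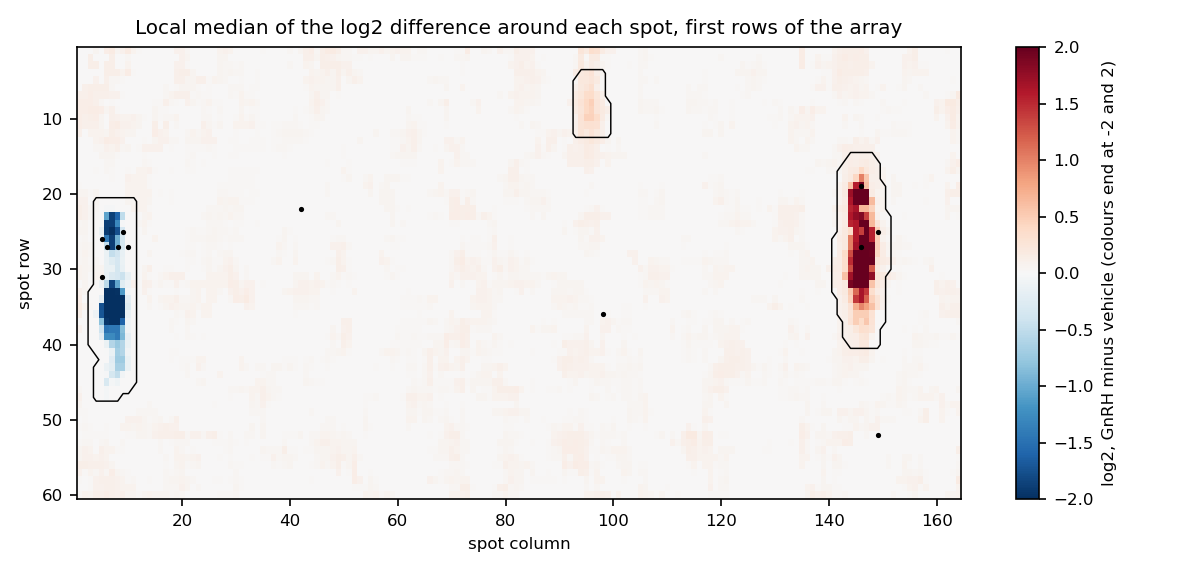
Median log2 difference (GnRH minus vehicle) of the spots around each spot, over the first 60 rows of the array by spot row and column; outlines are the 3 areas and dots are named genes. The area at columns 143 to 149 is brighter on the GnRH array (median 1.53) and that at columns 5 to 9 on the vehicle array (median -1.35).

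The probe of Egr1 lay on chromosome 18 at 35024395 to 35024454, that of Fos on chromosome 12 at 86817900 to 86817959, that of Npas4 on chromosome 19 at 4984356 to 4984415 and that of Fosb on chromosome 7 at 19888168 to 19888227, all in build mm9 as the files give them. An mm9 annotation was not used here, so exons and untranslated regions are not assigned.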

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

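Leaving out the areas, leaving out shared list members and the looser background call for counts at 2-fold and for lists were chosen after the data were seen; the other alternatives were planned. The cause of each move was not tested unless the setting itself shows it. Scaling by the median, quantile normalization, removal of a lowess trend and the authors' value table gave 60 to 67 higher and 28 to 32 lower genes. The 15 highest named genes stayed 2-fold higher under every planned setting of values, filter and probe rule, and 12 had a value outside the areas and stayed so. The count of 66 higher genes became 1259 with no filter on dim probes, 253 at 1.5-fold and 40 at 3-fold. The looser background call gave 552 higher and 311 lower genes. The count of 28 lower genes became 12 with normexp, 12 with no background correction, 760 with no filter, 9 with the stricter filter, 187 at 1.5-fold, 13 at 3-fold and 14 without the areas. Of the genes above background on 1 array only, the 67 of the GnRH array became 29 with normexp, 653 with the looser background call and 29 without the areas, and the 69 of the vehicle array became 25, 403 and 29. The rule for the largest differences shared 5 of its 21 genes with no filter, 11 with the stricter filter and 12 without the areas. The immediate-early median of 1.37 became 0.96 with no filter, 2.22 as a mean and 0.84 without shared members. As means, the SRF and actin-linked list gave 0.38 and the CREB-linked list 1.09. The median of the 4 gonadotrope and pituitary markers turned from -0.077 to 0.035 with no filter and to 0.035 with the mean over probes, and its percentile of 1.51 became 79.6 and 80.5, 4.64 with the looser background call (6 members), 11.96 with unmatched random lists and 22.7 as a mean. The percentile of the ErbB list fell inside the central 95% under 6 settings, to 96.7 with quantile normalization, 93.2 with normexp, 97.3 in the authors' table, 92.4 with no filter, 88.2 with the stricter filter and 96.4 with the looser background call. That of cholesterol synthesis genes did so with unmatched random lists (93.3) and as a mean (96.2), while that of heat shock proteins passed the range with quantile normalization (97.7). The stricter filter left 23 of the 26 lists with enough members. Of 1502 values of 140 named genes under 11 settings, 65 moved by more than the scanner error and 0 of those called 2-fold changed sign; Egr1 was 7.50 with normexp and 7.44 with no background correction. Signal over background limits the dim genes. Among the 261 probes with 10 spots well above background, single-spot differences varied by 0.21 in the dimmest 66 and 0.06 in the brightest 65. With 1 array per group no paired analysis was possible.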

Other observations

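The tests on other probes, on neurosecretory genes, on levels of epithelial markers, on Gnrh1 probes and on neighbouring transcripts were chosen after the results were seen; those on control spots, the count of epithelial markers and further gonadotrope genes were written before the values they use were seen. Several genes in no list, chosen after their values were seen, were also higher in the GnRH array at spots outside the 3 areas. The secreted stress cytokine gene Gdf15 was 2.99-fold higher (1.58 ± 0.20). Below 2-fold were Id3 (0.97), an inhibitor of basic helix-loop-helix factors, Csrnp1 (0.95), the tissue factor gene F3 (0.87), the small GTPase gene Rhob (0.83), Nfkbid (0.78), Tob1 (0.74) and the nuclear noncoding RNA Malat1 (0.72). Ppp1r15a, a phosphatase subunit of the integrated stress response, was at 0.67. Below 0, among bright genes outside the areas that were not 2-fold apart, were Asb13 (-0.77) and the synaptotagmin gene Syt10 (-0.66).

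The 2-fold differences inside the 3 areas form the first pattern. Of 94 genes 2-fold apart, 35 (37.2%) had spots in areas that hold 0.799% of probes. Control spots, which were not used to find the areas, were brighter there on the array that was brighter (13 spots, median log2 difference 4.35), consistent with a local blemish on each array. For 16 genes, unnamed transcripts among them, 1 probe inside was 2-fold apart and another lay outside. The probes outside had a median of 0.020 in the same direction (0 of them 2-fold), which argues against a response to GnRH for these 16 as a set. For 14 of the 16 the probes outside were within 1.5-fold. The largest values in the same direction were 0.68 and 0.61, both of unnamed transcripts. The same check on 3 genes 2-fold apart outside the areas gave a median of 0.72, with 1 of the 3 past 2-fold. Other probes thus did not always repeat a 2-fold difference outside the areas either. Only 8 of the 35 genes are among the 16. The other 27 have no other measured probe and stay open, among them Dusp1, Foxr1, Hbb-bh1, Yipf7, Ppp2r5e, Gabrr1, Pax6 and Insyn2b, as does Rrad. The areas were widened, and for 13 of the 35 the spots around had a median under 0.3 in the gene's direction (0.06 for Pax6 and 0.00 for Insyn2b, where the genes were lower).

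The second pattern is Gnrh1, the gene for the peptide that GT1-7 cells are known for, with 0 of 2 probes well above background on both arrays. All 18 neurosecretory and vesicle genes were, which argues against RNA of a line that is not neurosecretory. The count of epithelial markers well above background, 5 of 12, lay between the numbers set beforehand for and against an epithelial line such as that in the free-text description. Their levels, a check added after that count, argue against mouse epithelial RNA, though signals of different probes compare only roughly. Of the 12 markers, 0 reached the median signal of the measured genes on either array (762 and 715). Of the 18 neurosecretory genes, 17 did. Epcam, Cdh1, Krt8, Krt18 and Krt19 were at 9.18 or less and the brightest, Krt7, at 464 and 431; human RNA on these mouse probes was not tested. RNA of a pituitary gonadotrope line, under a wrong label, is a candidate explanation. Cga, Nr5a1, Pitx1 and Gnrhr were well above background on both arrays. So were 6 of 6 further gonadotrope transcription factors (Foxl2, Lhx3 and Nr0b1 among them), where at least 5 had been set as the number this explanation needs. Of these 6, Gata2 (188 and 182) and Lhx4 (219 and 201) lay under the median signal of the measured genes. The hormone subunit gene Lhb was dim (71.5 and 72.1), and Fshb was not well above background on either array. A gonadotrope line stays a hypothesis, since 19 of 23 GnRH neuron identity genes were also well above background on both arrays, and a mixed sample was not tested. With 0 bright probes, a probe that misses the transcript and a low level of the transcript cannot be told apart.

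The third pattern is the 15 transcripts without a symbol that were 2-fold higher outside the areas and had a position. A candidate explanation is transcription near induced genes, and 1 of the 15 lay within 100 kb of a 2-fold higher gene. That one, 4930447I22Rik (1.70), lay 954 bp from the probe of Ier2. Random draws of 15 such transcripts gave a mean of 0.10, and 994 of 10000 draws gave at least 1, so the number decides neither way and the other 14 stay unexplained.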
